A study of Mus musculus with 8 samples.

How the data were processed

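RNA sequencing was carried out on 8 libraries of mouse hepatic stellate cells, the vitamin A storing cells of the liver that turn into matrix-producing myofibroblasts when activated. The labels give 4 groups with 2 libraries each, named by replicate letters a and b: quiescent cells, activated cells, activated cells with miR-15a and activated cells with a control microRNA. Total RNA was extracted with TRIzol and made into TruSeq libraries for single-end sequencing on a NextSeq instrument, per the labels' protocols. The labels name C57BL/6J and SCID mice without saying which library came from which strain. They also do not say whether libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

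The submitters' processing notes name STAR, Subread and featureCounts and the genome build mm10, with no versions or settings. The deposited table holds 14162 genes by symbol and is named as read counts, but its values are not raw counts. All 8 libraries hold the same 910 distinct whole numbers, 10 genes in each library are tied at the maximum of 125636, and another 4 are tied at the next value. Totals lie between 10193036 and 10234768, 0.409% apart. The deposited values were therefore treated as a normalized score, as left by quantile normalization and rounding, a step that neither the labels nor the file header records. The sequencing depth of each library is unknown, so no counting interval is given. Genes at the shared maximum are saturated and cannot differ there. Below it, high values also lie on shared steps, for a reason not recorded, so libraries of a group can be tied. Fstl1, for example, was at 42360 ± 0 in activated cells and at 24105 ± 0 with miR-15a. The SE of such genes may understate the spread between libraries. The lowest mean of any gene was 1, so genes without signal had been removed before deposit.

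The plan fixed before the data were examined had assumed raw counts and a count model. Because the values are scores, limma (version 3.58.1, R 4.3.3) was run instead on log2(value + 5), and the planned count-model alternative was not run. Genes with a value of at least 10 in at least 2 libraries were tested, which left 13150. The fit estimated 4 group means over all 8 libraries, with 4 residual degrees of freedom, a variance prior that followed the mean level and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(value + 5) scale, which understates the change of low genes. The pseudocount and the filter were set after the unit of the table was known.

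On 5 simulated tables of 13150 genes for the comparison of miR-15a with the control microRNA, each with 200 changed genes, the procedure was tested on simulated data. It recovered 75.4% of genes changed by a log2 fold of 1 and 96.4% of those changed by 2, with 6.22 false calls per 100 calls. Random gene lists, tested in the same tables for activated against quiescent cells, passed an unadjusted p of 0.05 in 2.3% of cases. The simulated genes varied independently, so this does not test lists whose genes are correlated. The simulated values were also not quantile-normalized, tied at steps or cut at a ceiling, and only the 200 genes differed between groups. These rates may therefore not hold for the deposited values.

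Before the data were examined, 37 gene lists were written for stellate cell states, matrix, signalling, cell cycle, stress and metabolic pathways and other liver cell types. Of 794 list entries 658 were measured. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The estimated setting also rests on fewer degrees of freedom, the 4 residual ones, so it can lose calls for that reason. Genes named in the text were the 10 largest increases and 10 largest decreases per comparison among called genes with a mean of at least 5 per 1000000 and no overlap between groups, leaving out unnamed gene models. To these were added up to 4 members of each list with the smallest p, a fixed set (Acta2, Col1a1, Timp1, Pparg, Bcl2, Ccnd1, Ccne1, Dleu2), and the 10 genes with the smallest adjusted p that rose on activation, fell with miR-15a and carried a seed site. Any other gene named was chosen after its values were seen, as the text says there.

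Seed sites were sought in the longest annotated 3′ UTR of each gene (GENCODE M21 on GRCm38, the assembly behind mm10, positions from 1). The site was TGCTGCT, the complement of positions at the 5′ end of miR-15a. An annotated 3′ UTR was found for 13032 genes (92.0%), and 3115 of these had a site. The same measure was taken for all 210 heptamers of that base composition. Alternatives covered scaling, filters, the samples in the fit, a replicate block, a fold limit, each library left out in turn, site definitions and set definitions. Pseudocounts of 1 and 20, another variance prior, limits to genes at 100 or more in both activated groups and sets without markers of other cells were chosen after seeing the data. Scripts used Python 3.11.15.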

Results

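The transcriptomes of mouse hepatic stellate cells were measured by RNA sequencing in quiescent cells, activated cells, activated cells with miR-15a and activated cells with a control microRNA, with 2 libraries per group. The purpose given for the series was to find genes likely to be targets of miR-15a. The deposited values are normalized scores, so the depth of the libraries is unknown. Replicate libraries correlated at a Pearson r of 0.986 to 0.990 across genes on the log2 scale. The first principal component held 84.9% of the variance. It placed the quiescent libraries at -152 and -150, the activated libraries at 71.9 and 75.5, the control microRNA libraries at 65.3 and 60.1 and the miR-15a libraries at 16.01 and 12.9.

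**Figure D1:**
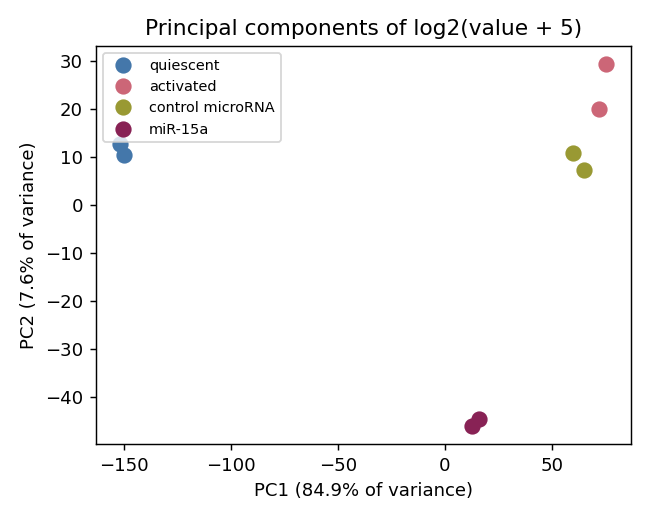
Principal components of log2(value + 5), with the share of variance on each axis and 1 point per library, coloured by group. On the first axis the quiescent libraries lie apart from the others, and the miR-15a libraries (16.01 and 12.9) lie between the quiescent and the control microRNA libraries. On the second axis (7.61% of the variance) the miR-15a libraries lie apart at -44.5 and -46.0, with the quiescent libraries at 12.7 and 10.3 and the control microRNA libraries at 7.27 and 10.8.

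The comparison of activated with quiescent cells was used to describe activation. The quiescent libraries also held abundant endothelial and macrophage transcripts, given below, so it is not a comparison of stellate cells alone. Contractile and matrix genes were among those that rose. Cnn1, which encodes the smooth muscle protein calponin, rose from 1.5 ± 0.71 to 5234.5 ± 156 (mean ± SD, n = 2 each; log2 fold change 9.66 ± 0.08 SE, adjusted p = 5.2e-10, limma). Col1a1, a chain of type I collagen, rose by 7.28 ± 0.22, and Timp1, an inhibitor of matrix proteases, by 7.86 ± 0.40. Acta2, the smooth muscle actin used as the standard activation marker, reached the ceiling of 125636 in both activated libraries against 43 and 51, so its log2 fold change of 11.24 is bounded by the normalization. Lox, which cross-links collagen, stood at the same ceiling.

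Of 33 measured genes of the fibrillar matrix list, 31 rose and 2 fell (adjusted p = 2.9e-11, camera; 31 and 2 adjusted over the list alone), and this call held with an estimated correlation (adjusted p = 0.044). Of 24 contractile genes 23 rose and 1 fell (adjusted p = 9.2e-08; 23 and 1 adjusted over the list alone), also with an estimated correlation (adjusted p = 0.044). All 30 mitotic genes rose, among them Prc1 (3.94 ± 0.07) and Tpx2 (3.91 ± 0.12), with an adjusted p of 1.2e-08 and all 30 adjusted over the list alone. With an estimated correlation their adjusted p was 0.079. Of 20 markers of quiescent stellate cells 15 fell and 5 rose (adjusted p = 8.7e-04; 15 and 5 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). Vipr1, a receptor for vasoactive intestinal peptide, fell by 7.28 on the log2 scale and Plin2, a lipid droplet coat protein, fell by 2.32. Lrat, Gfap, Lhx2, Colec10 and Tcf21 were among the members of this list with no measured value. Pparg, an adipogenic transcription factor on that list, went the other way, from 58 ± 7.07 to 367.5 ± 14.8 (log2 fold change 2.57 ± 0.13, adjusted p = 7.9e-07).

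Markers of endothelial cells, macrophages and hepatocytes and genes of the interferon response fell. All 21 measured endothelial markers and all 21 macrophage markers were lower in the activated libraries (adjusted p = 1.2e-10 and 1.5e-11; all 21 of each adjusted over the list alone). With an estimated correlation the adjusted p was 0.19 and 0.079. Stab2, a scavenger receptor of sinusoidal endothelium, stood at 125636 and 58193 in the quiescent libraries and at 20 and 3 in the activated ones. Marco, a macrophage scavenger receptor, fell from 10928 ± 600 to 0.5 ± 0.71. Of 25 hepatocyte genes 23 fell and none rose (23 adjusted over the list alone; adjusted p = 1.2e-05, and 0.47 with an estimated correlation). All 34 interferon response genes fell, and Oasl1 fell by 9.53 on the log2 scale (adjusted p = 6.3e-15 for the list, all 34 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation). Some other cell types did not follow. Both measured cholangiocyte markers rose, Spp1 by 3.37 and Sox9 by 1.90. Of 8 markers of mesothelial cells and portal fibroblasts 5 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.43, and 0.53 with an estimated correlation), and of 5 smooth muscle markers 3 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.11, and 0.23 with an estimated correlation).

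Over all genes 5968 were higher and 4483 lower in activated cells, of 13150 tested. With median-ratio scaling, which shifted the median of all genes by -0.22, the split was 5070 higher and 5208 lower. The groups also differed in genes of the sex chromosomes, which were chosen after their values were seen. Xist, expressed from the inactive X, was at 8724 ± 0 in quiescent and 95 ± 105 in activated libraries, and the Y-linked Ddx3y at 42 ± 2.83 and 2588 ± 25.5. In the control microRNA and miR-15a libraries Xist was at 4200 ± 1170 and 3373 ± 0, and Ddx3y at 1275 ± 9.9 and 1026 ± 28.3. By these genes the quiescent libraries were largely from female cells and the activated ones largely from male cells, with both microRNA groups between. The quiescent and activated groups therefore differed in their animals. The labels do not say whether the other groups share animals, so any comparison of groups can include a difference between animals.

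**Figure D2:**
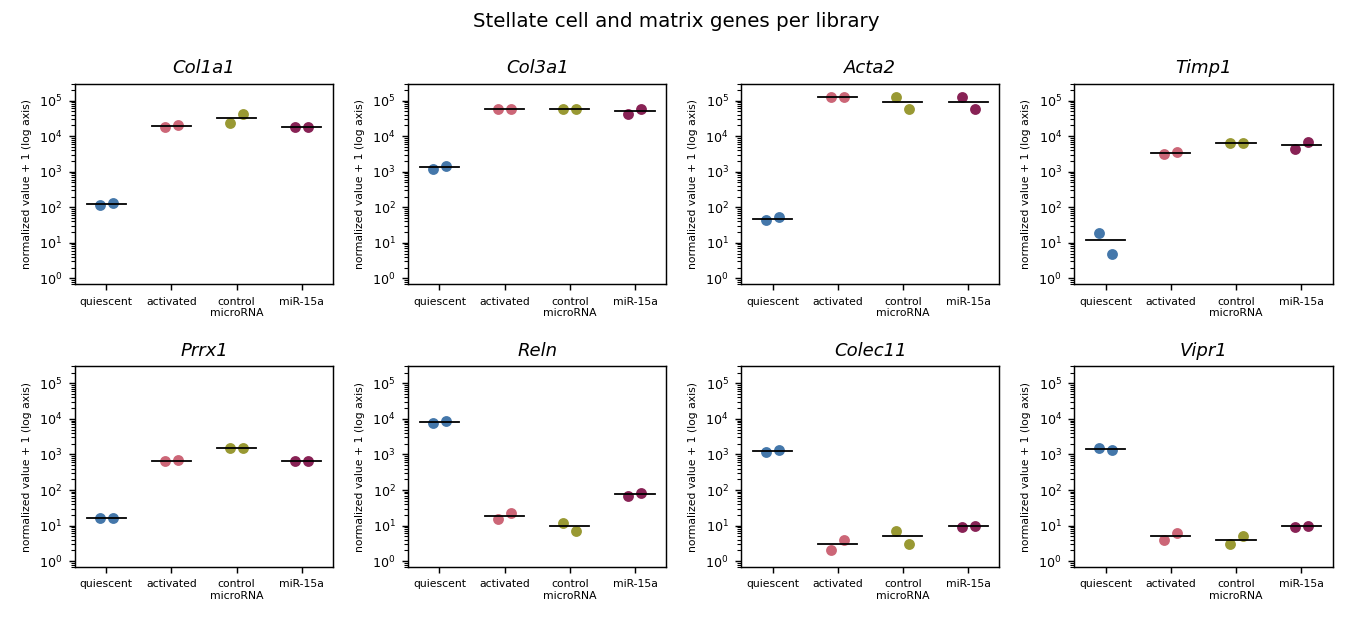
Normalized value plus 1 on a log axis for 8 stellate cell and matrix genes, with 1 point per library and a line at the group mean. Acta2 reaches the ceiling of 125636 in the activated libraries, and Vipr1 and Colec11 have means of at most 8.5 in every group of activated cells, while Reln is at 18 in activated cells, 8.5 with the control microRNA and 74.5 with miR-15a.

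The comparison of miR-15a with the control microRNA, both in activated cells, addressed the effect of miR-15a. Most fibrillar matrix genes and some mitotic genes were lower with miR-15a. Of 33 fibrillar matrix genes 23 fell and none rose (adjusted p = 2.1e-08; 23 adjusted over the list alone; adjusted p = 0.088 with an estimated correlation). Col1a1 fell by 0.77 on the log2 scale (SE 0.22, adjusted p = 0.036, limma) and Plod2, a collagen lysyl hydroxylase, fell by 1.10. Of 30 mitotic genes 13 fell, and the proliferation marker Mki67 fell by 1.01 (adjusted p = 1.0e-05; 14 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). Notch3, a receptor of mural cells, fell by 1.54 and Eln, which encodes elastin, fell by 1.68. The call of Col1a1 was lost (adjusted p 0.063 to 0.13) without either library of the quiescent, activated or miR-15a group and with no filter (0.065).

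Other groups also fell in part. Of 16 basement membrane genes 10 fell (10 adjusted over the list alone; adjusted p = 7.6e-05), of 21 targets of YAP 12 fell and 1 rose (16 and 2 adjusted over the list alone; adjusted p = 3.3e-04), and of 25 myofibroblast genes 10 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.031). With an estimated correlation each of these 3 lists had an adjusted p of 0.14. Postn, a matricellular protein of myofibroblasts, fell by 1.35. Acta2 was at 125636 and 58193 in both groups, and Timp1 did not pass (log2 fold change -0.24 ± 0.40). Of 14 genes of the microRNA machinery 8 fell (10 adjusted over the list alone; adjusted p = 0.0033, and 0.15 with an estimated correlation).

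Transcripts of endothelial cells and macrophages were among the largest increases. Marco rose from 2.5 ± 2.12 to 1238.5 ± 162 (log2 fold change 7.40 ± 0.21, adjusted p = 1.5e-06), and Pecam1, an endothelial adhesion molecule, from 33 ± 21.2 to 2717.5 ± 209. Of 21 endothelial markers 18 rose and 1 fell (19 and 1 adjusted over the list alone; adjusted p = 2.0e-12, and 0.14 with an estimated correlation). All 21 macrophage markers rose (all 21 adjusted over the list alone, camera adjusted p = 7.8e-21, and 0.088 with an estimated correlation). Of 25 hepatocyte genes 4 rose and none fell (4 adjusted over the list alone, camera adjusted p = 0.0016, and 0.57 with an estimated correlation). Both measured neutrophil markers rose, and both measured cholangiocyte markers fell. All 34 interferon response genes rose, with a median of 2.56 (all 34 adjusted over the list alone; adjusted p = 7.2e-28, and 0.12 with an estimated correlation). Of 21 inflammatory genes 15 rose and 2 fell, including the chemokine gene Ccl2 at 3.88 ± 0.07 (15 and 3 adjusted over the list alone; adjusted p = 5.3e-08, and 0.088 with an estimated correlation).

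Of 20 quiescent stellate markers 8 rose and 3 fell (8 and 5 adjusted over the list alone; adjusted p = 0.033, and 0.23 with an estimated correlation). Ednrb, an endothelin receptor that endothelial cells also express, rose by 8.16 ± 0.42, and Hgf, hepatocyte growth factor, by 1.35 ± 0.09. Reln, an extracellular glycoprotein, rose from 8.5 ± 3.54 to 74.5 ± 10.6 (log2 fold change 2.58 ± 0.23, adjusted p = 2.6e-04), against 8224 ± 707 in quiescent cells. Colec11, a collectin, was at 4 ± 2.83 and 8.5 ± 0.71 and did not pass (0.62 ± 0.25), against 1270 ± 87.7 in quiescent cells. Both were chosen after their values were seen. Pparg did not pass (-0.21 ± 0.13).

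Over all genes 1897 were higher and 2029 lower with miR-15a, and 679 and 219 when a log2 fold change over 1 was also required. With median-ratio scaling the balance turned, to 2255 higher and 1639 lower. The total of 3926 fell to 2375 without miR-15a library b and to 2381 without control library b. It was 2093 when the other groups were left out of the fit.

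**Figure D3:**
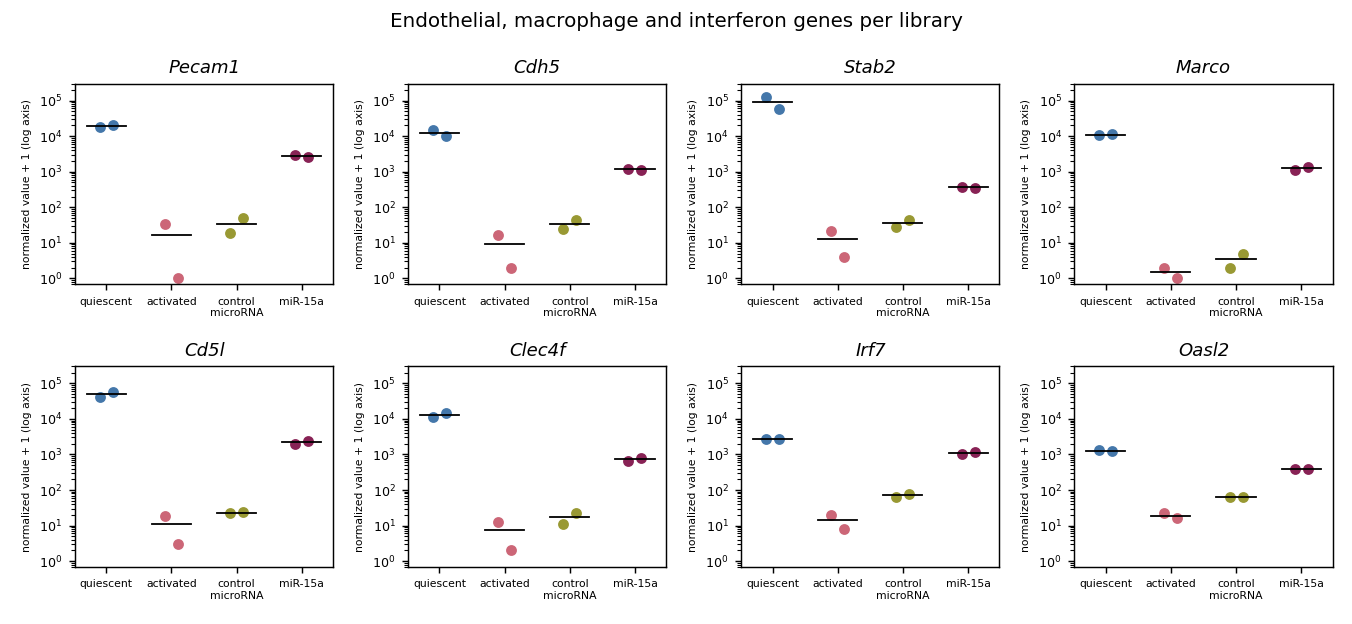
Normalized value plus 1 on a log axis for 8 endothelial, macrophage and interferon genes, with 1 point per library and a line at the group mean. The miR-15a libraries lie between the control microRNA and the quiescent libraries, as for Marco at 1238.5, 2.5 and 10928.

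**Figure D4:**
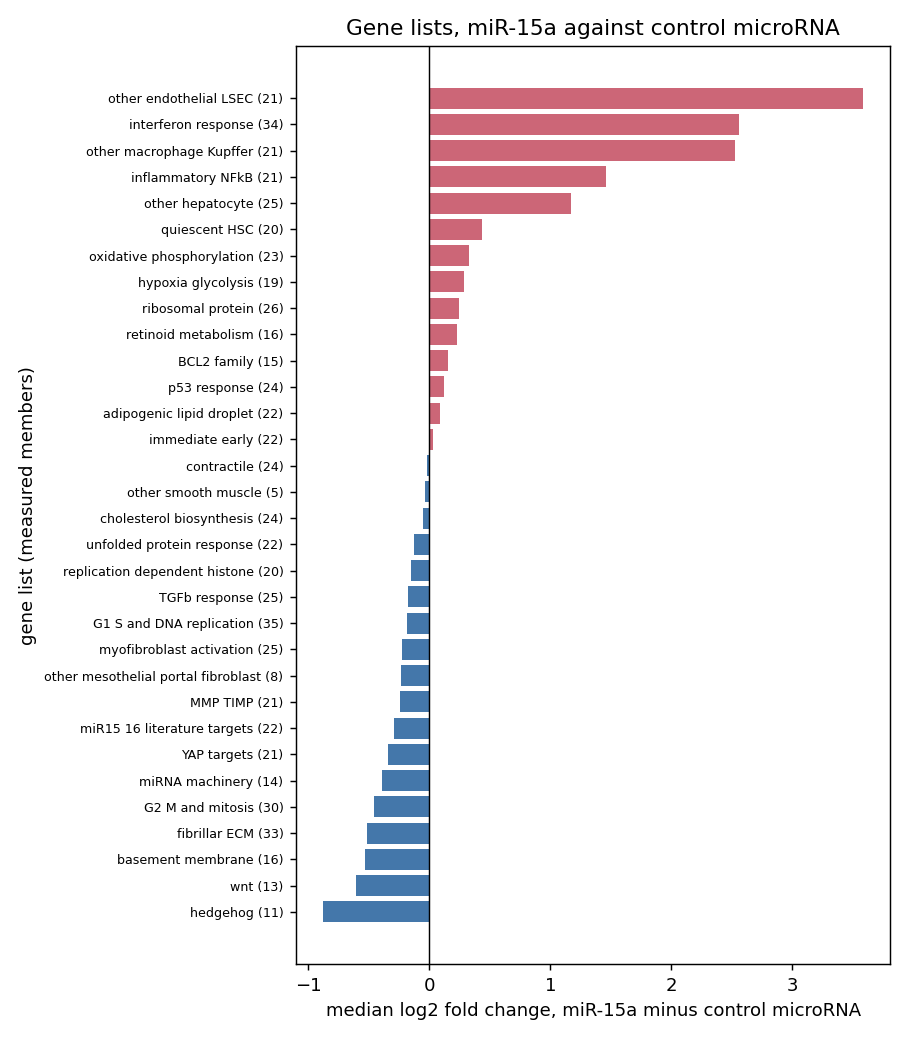
Median log2 fold change of each gene list, miR-15a minus control microRNA, with the number of measured members in parentheses. Interferon genes (2.56), macrophage markers (2.52) and endothelial markers (3.59) lie highest among the lists named in the text.

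Genes changed on activation tended to move the other way with miR-15a. Of 3160 genes that rose on activation by a log2 fold change over 1, 840 fell and 143 rose with miR-15a, with a median of -0.19 (camera p = 5.8e-08, p = 0.031 with an estimated correlation, fry p = 9.2e-04). Of 2859 that fell on activation, 1120 rose and 193 fell, with a median of 0.31 (camera p = 6.2e-22, p = 0.0015 with an estimated correlation). Across genes, which are not independent replicates, the fold changes correlated at r = -0.60 (Spearman rho = -0.37), and at r = -0.41 among genes at 100 or more in both activated groups. The comparisons share no library. Endothelial and macrophage markers, which fell on activation and rose with miR-15a, are among these genes. There were 1226 genes higher on activation and lower with miR-15a, against 921 for independent lists, and 1357 the other way, against 647. The 1226 fell to 668 without miR-15a library b and to 718 without control library b.

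Seed sites were more frequent among genes lower with miR-15a. Of 1974 such genes with an annotated 3′ UTR, 651 (33.0%) carried TGCTGCT, against 22.8% of the other genes (odds ratio 1.67, 95% interval 1.499 to 1.85, Fisher's exact test, two-sided, p = 6.4e-21). Within 20 bins of 3′ UTR length the odds ratio was 1.11, with an interval of 0.993 to 1.25, and it ranked 82 from the highest of 210 heptamers of the same composition. The highest of these, TTGCGCT at 1.67, occurs in only 214 genes, and odds ratios of rare heptamers are uncertain. The 3016 genes with a site had a median log2 fold change of -0.11 and the 9336 without of -0.05. The set did not pass camera at the preset correlation (p = 0.068) and did with an estimated correlation (p = 0.0010), a call that differs between these choices. The difference of -0.064 ranked 71 from the lowest of the 210 heptamers, many of which occur in far fewer genes. With genes split by 3′ UTR length it was 0.015 among the 4118 with the shortest, 0.0048 among the 4117 in the middle and -0.050 among the 4117 with the longest. Against activated cells the difference was -0.032 (camera p = 0.46 at the preset and 0.026 with an estimated correlation), and in the control microRNA against activated cells it was 0.038 (p = 0.20 and 0.0039), so part of the difference against the control microRNA lies in the control group.

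Of 1226 genes higher on activation and lower with miR-15a, 1200 had an annotated 3′ UTR and 380 of these (31.7%) carried a site. The share among the other genes was 23.6%, and these shares were not adjusted for 3′ UTR length. Many of the 380 would thus carry a site without any effect of miR-15a. The smallest adjusted p against the control microRNA belonged to Prrx1, a homeobox transcription factor of mesenchymal cells (chromosome 1, 163245119 to 163313710, minus strand, GRCm38), which was lower by 1.20 ± 0.07. It stood at 670 ± 11.3 in activated cells, 654.5 ± 12.0 with miR-15a and 1510.5 ± 6.36 with the control microRNA, so the difference comes from a higher control group and Prrx1 did not pass against activated cells (-0.03 ± 0.07). Its site lies at 163254103 to 163254109 in exon 3 of 3, in the 3′ UTR of the transcript with the longest one (4891 bases). The gene extends past the end of that transcript, and other Prrx1 transcripts may lack the site. Bmpr1a, a receptor for bone morphogenetic proteins (chromosome 14, 34410734 to 34503341, minus strand), fell by 0.99 and has its site at 34412620 to 34412626 in exon 13. Lats1, a kinase of the Hippo pathway (chromosome 10, 7681214 to 7716460, plus strand), fell by 0.95 and has 4 sites, the first at 7713670 to 7713676 in exon 8. Fstl1, Itga1, Tln2, Plxdc2, Sh3pxd2a, Cast and Adamts12 were also among the 10 with the smallest adjusted p, with decreases from -0.63 (Cast) to -1.15 (Plxdc2). Fstl1 moved between shared steps of the values, from 42360 ± 0 with the control microRNA to 24105 ± 0, so its adjusted p may be too small. Of 22 genes described as targets of the miR-15 family before, 10 fell and 2 rose (12 and 2 adjusted over the list alone; adjusted p = 0.034, and 0.14 with an estimated correlation). Against activated cells 5 fell and 3 rose (5 and 3 adjusted over the list alone; adjusted p = 0.52, and 0.55 with an estimated correlation), and in the control microRNA against activated cells 3 rose and none fell (3 adjusted over the list alone; adjusted p = 0.097, and 0.33 with an estimated correlation). Bcl2, an inhibitor of apoptosis, fell by 0.47 (adjusted p = 0.048) and Ccnd1, cyclin D1, rose by 0.25 (adjusted p = 0.021). The call of Bcl2 was lost without 7 of the 8 libraries in turn and that of Ccnd1 without any 1 of the miR-15a or control libraries. Ccne1, cyclin E1, did not pass (-0.17 ± 0.12), nor did Dleu2, the host transcript of miR-15a (0.09 ± 0.13).

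Against activated cells with no microRNA named, matrix genes were again lower and macrophage markers higher with miR-15a. Eln fell by 2.96 and Myh11, smooth muscle myosin, fell by 2.59, while Marco rose by 7.82 ± 0.21. All 21 macrophage markers rose (all 21 adjusted over the list alone; adjusted p = 2.6e-19, and 0.11 with an estimated correlation). Of 33 fibrillar matrix genes 21 fell and none rose (21 adjusted over the list alone; adjusted p = 2.9e-06, and 0.12 with an estimated correlation). Other lists had calls that differed from those against the control microRNA, a difference that was not tested. Of 24 contractile genes 12 fell and 3 rose here (13 and 3 adjusted over the list alone; adjusted p = 0.0088, and 0.15 with an estimated correlation), and 7 fell and 2 rose against the control microRNA (7 and 2 adjusted over the list alone; adjusted p = 0.59, and 0.65 with an estimated correlation). The microRNA machinery, myofibroblast and quiescent stellate lists did not pass here (adjusted p = 0.15, 0.071 and 0.071). In all 2204 genes were higher and 2841 lower. With median-ratio scaling the balance turned, to 2798 higher and 1929 lower, and the total fell from 5045 to 2764 without activated library b.

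The control microRNA libraries also differed from those of activated cells. Cxcl12, a chemokine, rose by 3.44 ± 0.10 and Sfrp1, a secreted Wnt antagonist, by 3.49 ± 0.24, while Igfbp2, which binds insulin-like growth factors, fell by 2.05. Of 34 interferon response genes 21 rose (27 adjusted over the list alone; adjusted p = 4.6e-15, and 0.22 with an estimated correlation). Of 24 contractile genes 9 fell (11 adjusted over the list alone; adjusted p = 0.0072, and 0.22 with an estimated correlation), and of 5 smooth muscle markers 3 fell (4 adjusted over the list alone; adjusted p = 0.011, and 0.22 with an estimated correlation). Of 21 endothelial markers 4 rose and 1 fell, with a median of 0.81 (7 and 1 adjusted over the list alone; adjusted p = 1.1e-04, and 0.47 with an estimated correlation). Xist had the largest increase, 5.94 ± 0.73. The genes that rose on activation had a median of -0.14 here and those that fell on activation 0.14, and these comparisons share the activated libraries. There were 944 higher and 869 lower genes, with 1175 and 637 under median-ratio scaling and 1009 and 1630 with no filter. The total of 1813 fell to 490 without activated library b and to 276 when the other groups were left out of the fit.

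Compared with quiescent cells, 4883 genes were higher and 4525 lower with miR-15a, and 5356 and 4340 with the control microRNA. With median-ratio scaling both balances turned, to 4425 and 5001 and to 4656 and 4960. Group means correlated across genes at 0.782 between quiescent and miR-15a cells and at 0.673 between quiescent and control microRNA cells.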

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

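The directions of the 2 activation sets held under every alternative run, and no called gene named for a comparison reversed. The seed-site difference over all genes stayed negative under the alternatives run for it, but with genes split by 3′ UTR length it was negative among the 4117 with the longest (-0.050) and above 0 among the shortest and the middle (0.015 and 0.0048). Whether higher or lower genes were more numerous did not hold. For miR-15a against the control microRNA this turned in 9 of 19 alternatives, including median-ratio scaling (2255 higher, 1639 lower) and 6 of the 8 single libraries left out. For miR-15a against activated it turned in 4 of 18, for the control microRNA against activated in 3, for miR-15a against quiescent in 2, and for activated and the control microRNA against quiescent in 1 each, median-ratio scaling. Pseudocounts of 1 and 20, another variance prior, the limit to genes at 100 or more in both activated groups and sets without markers of other cells were chosen after seeing the data. The labels do not say whether letters a and b pair the libraries. Correlations of deviations between groups were small (-0.07 to 0.09), which does not settle it. A replicate block gave 3776 calls for miR-15a against the control microRNA instead of 3926. For the control microRNA against activated cells it gave 1490 instead of 1813. Requiring a log2 fold change of at least 1 left 6020 calls for activated against quiescent, 898 for miR-15a against the control microRNA, 1178 for miR-15a against activated, 322 for the control microRNA against activated, and 5214 and 5634 for miR-15a and the control microRNA against quiescent cells, because fewer genes can pass. With only the groups compared in the fit, and so fewer samples, miR-15a against the control microRNA had 2093 calls and the control microRNA against activated 276. Leaving out each library in turn gave 2375 to 3613 calls for miR-15a against the control microRNA, 2764 to 5128 for miR-15a against activated and 490 to 1688 for the control microRNA against activated. It gave 668 to 1196 genes higher on activation and lower with miR-15a. The lone library of a group is then assumed to vary like the others. With an estimated correlation 0 of 21 list calls of camera remained for miR-15a against the control microRNA. This included lists with an estimate below the preset of 0.01, such as the inflammatory genes (-0.029, camera p from 8.3e-09 to 0.0032). More than the correlation therefore differs between these settings. With a preset, camera takes its degrees of freedom from the number of genes. With an estimate it takes the 4 residual ones. A call lost with an estimate does not by itself show that genes of a list are correlated. The correlation of fold changes ranged from -0.54 (without control library a) to -0.62 (without control library b) and was -0.41 among genes at 100 or more in both activated groups. In those genes the seed-site difference was -0.0733 and passed camera at the preset correlation (p = 0.033). With a library left out it ran from -0.0841 to -0.0550, and it passed at the preset correlation without control library a (p = 0.042). The cause was not tested. Of the genes named in any comparison, Col1a1, Bcl2, Ccnd1, Tpx2, Igfbp2, Vipr1, Ddx3y and Sfrp1 lost their calls for miR-15a against the control microRNA with some single libraries left out, as did Sdhd for activated against quiescent. Col1a1, Bcl2, Igfbp2 and Vipr1 also lost them under some other alternatives. The planned count model was not run because the values are not counts. Saturation at the ceiling, ties of high values at shared steps and the unknown depth limit what can be said of the highest and lowest genes.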

Other observations

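Genes of oxidative phosphorylation and ribosomal proteins and some of the BCL2 family were higher with miR-15a. Of 23 genes of oxidative phosphorylation 13 rose and none fell against the control microRNA (17 adjusted over the list alone; adjusted p = 5.0e-06, and 0.14 with an estimated correlation), such as Sdhd, a subunit of succinate dehydrogenase, by 0.79 ± 0.08. Of 26 ribosomal protein genes 13 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 3.4e-04, and 0.14 with an estimated correlation). Of 15 genes of the BCL2 family 5 rose and 1 fell, including the proapoptotic Bax by 1.05 ± 0.10 (5 and 1 adjusted over the list alone; adjusted p = 0.012, and 0.14 with an estimated correlation). Cholesterol biosynthesis (3 of 24 higher, 5 lower; adjusted p = 0.98) and retinoid metabolism (adjusted p = 0.13) did not pass. Endothelial and macrophage markers rose in the same libraries. In control microRNA library b the hepatocyte gene Alb, chosen after its values were seen, was at 640 against 48 in library a.

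In all, 7 tests of explanations were run on 3 patterns. Of these, 6 were chosen only after the result was seen: those on endothelial and macrophage transcripts, and those on seed sites, for which site frequency by 3′ UTR length and a rank among heptamers had been looked at. The bounds of the test of dilution were set before its value was computed. By Xist and Ddx3y the groups differed in the sex of their cells, with both microRNA groups between quiescent and activated cells. Whether this, or other differences between the animals, accounts for any pattern was not tested and stays open.

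Endothelial and macrophage transcripts were abundant in the miR-15a libraries and also in the quiescent ones. Carry-over of RNA or reads from the quiescent libraries was tested on 154 genes at 500 or more there and at 30 or less in the activated and control groups. The rank correlation of quiescent and miR-15a means was 0.607 times that of the miR-15a libraries with each other, between the bounds set for that test (0.8 and 0.5), so it did not decide. A further test, added because of that outcome, found ratios to the quiescent level spread 3.93 times as widely as those between the miR-15a libraries, which argues against 1 carry-over share, although it was chosen knowing the earlier value. Cells of these types in the cultures, with 85.7% of endothelial markers higher against a bound of 90%, fell between the bounds set and stay open. So does a return of stellate cells toward quiescence, whose markers recovered 0.347 times as much as those of the other cells, also between its bounds. The shares recovered by the stellate markers ran from -57.7% (Pth1r) to 93.8% (Ednrb, which endothelial cells also express), so that ratio is not of stellate cells alone.

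Genes that rise on activation were lower in the miR-15a libraries. If RNA of other cells only diluted that of stellate cells, genes nearly absent from quiescent cells would fall by 1 amount. Across 139 such genes the SD of the log2 fold changes was 4.22 times their median standard error (0.51 against 0.12), with 62 lower and 8 higher, past the bound of 2. That bound was wrong, as a comparison made afterwards showed: in the control microRNA against activated cells the SD of the same genes was 0.61, so groups differ that widely without miR-15a. The test therefore does not decide, and dilution stays open, as does an effect of miR-15a on the stellate cells.

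TGCTGCT sites were more frequent among genes lower with miR-15a. Longer 3′ UTRs of these genes may account for it, since the interval of the odds ratio within length bins reached down to 0.993. For the base composition of the heptamer, TGCTGCT ranked 82 of 210, but this rank does not decide. Many of the heptamers occur in far fewer genes and have uncertain odds ratios. The highest, TTGCGCT, occurs in 214 genes (1.67, interval 1.24 to 2.25), against 3016 for TGCTGCT. Base composition therefore stays open. Direct repression of single genes by miR-15a stays open, because a set-wide measure does not speak to each gene.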
